A study of Mus musculus with 24 samples.

How the data were processed

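The deposited data comprised 24 libraries from Ocy454 mouse osteocytic cells, 3 for each combination of vehicle, LPA, 1,25D or both agents with 2 h or 8 h of treatment. Total RNA was extracted with an RNeasy kit and libraries were made with a DNBSEQ Fast RNA kit, per the labels' protocols. Doses are not given in the sources used here. Each library had its own table of 139145 Ensembl transcripts. The authors deposited estimated counts per transcript, which need not be whole numbers and are not scaled between libraries, per the file headers. The tables also hold TPM per transcript, normalised by the authors for effective length and depth, per the file headers. The quantifier is not given in the sources used here, and the genome build is mm39, per the submitters' processing notes. Groups were taken from the sample titles. The treatment letters in the names of the deposited tables differ from the titles for the single treatments, and expression of Cyp24a1 and Vdr goes against the titles, so single treatments are described as labelled.

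Transcripts were assigned to genes by their Ensembl identifiers with the GENCODE M21 annotation, which is on the older build GRCm38 and was used for gene names, transcript GC content and length, not for positions. It matched 135078 transcripts, which held 99.45 to 99.60% of each library's counts. Unmatched transcripts were left out. Estimated counts were summed to 49172 genes and rounded to whole numbers, and 34882 genes had at least 1 count in a library. Totals were 32.96 to 33.84 M per library. Libraries of a group differed by more than sampling noise (chi-square per degree of freedom 7.09 to 134), so no library was treated as a duplicate.

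The main test was edgeR 4.0.16 in R 4.3.3 with its quasi-likelihood F test (robust), TMM scaling and the filterByExpr filter at its minimum count of 10, which kept 16424 genes. All 8 groups entered 1 fit without covariates, so they shared 1 estimate of the spread, with 16 residual and 5.0 prior degrees of freedom and a common biological coefficient of variation of 0.131. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a comparison, with a threshold of 0.05, and fold changes are on the log2 scale with standard errors. CPM values use TMM-scaled library sizes. The 16 comparisons were each treatment against vehicle and both agents against each single treatment at both times, the interaction at each time (both agents − LPA − 1,25D + vehicle, log2 scale), vehicle at 8 h against 2 h, and the difference of each treatment effect between 8 h and 2 h. For genes with 3 or fewer counts in a group the ratio of summed counts is given with a 95% exact interval, which covers counting error only.

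A total of 25 gene lists, holding 484 members, were fixed before the data were examined: vitamin D receptor targets; FGF23 production and phosphate handling; LPA receptors and LPA metabolism; immediate early genes; ERK MAPK feedback and targets; SRF and MRTF actin targets; YAP and TEAD targets; IL-12 and IL-6 family cytokines and receptors; NF-kB targets and chemokines; osteocyte markers; osteoblast and bone matrix genes; Wnt signalling and bone remodelling; DNA replication and G1/S; mitosis; glycolysis and glucose uptake; cholesterol synthesis and uptake; integrated stress and unfolded protein response; heat shock; mitochondrially encoded genes; interferon response; and markers of adipocytes, chondrocytes, macrophages and blood cells, endothelium and skeletal muscle. Lists with at least 5 tested members, 21 in number, were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over 252 pairs of list and comparison within a time, and again with an estimated correlation. Genes named in the text followed a rule. Fgf23, Il12a, Cyp24a1, Vdr and Lpar1 were always eligible. In each comparison with vehicle, the 8 largest rises and falls were taken among genes past the threshold with a mean of at least 1 CPM over the compared groups, a name other than a clone or predicted gene number, and replicates that do not overlap, and 5 each way in the other comparisons, without the overlap criterion for interactions and time differences. Lists with 3 or more members past the threshold supplied up to 2 risers and 2 fallers with the smallest p. Unnamed gene models were passed over. Some genes that met the rule are not reported here. From the list members so chosen, a part is printed.

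Alternatives planned before the data were examined were median-of-ratios scaling, no filter on low counts, DESeq2 1.42.0, a fit of the compared groups alone, the replicate number as a block, leaving out each library in turn, and an estimated correlation for lists. A further 4 were chosen after seeing the data: counts from length-scaled TPM, correction for GC content and transcript length, a covariate holding each library's score on the first principal component of deviations from group means, and leaving out the 2 libraries highest on that axis. The axis held 15.6% of the variance within groups. Scores on it were taken from deviations from the mean of all libraries, so they also hold differences between groups. The axis was derived from the same genes that were tested, so the covariate takes up part of their residual variation. Larger counts with it are therefore not independent evidence of more changed genes. The tests were tried on simulated data with the real means and library sizes. For the libraries labelled LPA against vehicle at 8 h, edgeR recovered 38.8, 56.7 and 83.3% of genes changed 1.5-fold, 2-fold and 4-fold among 15989 genes, and 4.8% of its calls were false; for DESeq2, with 16421 genes, 20.2% were false. For the interaction at 8 h edgeR recovered 16.4, 64.2 and 69.7% among 16026 genes with 5.66% false calls. Simulated genes varied independently, with a spread common to all groups. These rates therefore do not cover variation shared by genes or unlike spread between groups.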

Results

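RNA was sequenced from Ocy454 cells, a mouse osteocytic line, after vehicle, lysophosphatidic acid (LPA), 1,25-dihydroxyvitamin D (1,25D) or both agents for 2 h or 8 h. LPA is a bioactive lysophospholipid that signals through G protein-coupled receptors. The active vitamin D hormone, 1,25D, acts through the nuclear receptor encoded by Vdr. The study asked how the agents affect synthesis of FGF23, the phosphate-regulating hormone of bone, and which pathways they engage at the early and the later time. Each of the 8 groups held 3 libraries, so 24 libraries entered the comparisons, and n = 3 for every group mean and SD given here. Total estimated counts ran from 32.96 to 33.84 M per library, with a median of 33.66 M. Between 21018 and 23194 genes had at least 1 read in a library. Mitochondrially encoded genes took 9.01 to 16.92% of the counts, and the highest share belonged to vehicle replicate 2 at 8 h. No label says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples. The first principal component of all libraries held 21.4% of the variance and the second 11.8%.

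Cyp24a1, which encodes the vitamin D 24-hydroxylase and is a direct target of the vitamin D receptor, and Vdr itself served to check the treatment labels. Both went against the labels of the single treatments. At 8 h the 3 libraries labelled 1,25D held 1 Cyp24a1 count in all, as did the 3 vehicle libraries, a ratio of 1.01 with a 95% counting interval from 0.0129 to 79.4. The 3 libraries labelled LPA held 102 counts, a ratio of 100 to vehicle (17.6 to 3990), and the libraries given both agents held 87, a ratio of 91.2 (15.9 to 3640). Each library labelled LPA had between 25 and 48 Cyp24a1 counts at 8 h, and each given both agents between 24 and 35. At 2 h the counts were 1 for vehicle, 1 for the libraries labelled 1,25D, 10 for those labelled LPA and 6 for both agents. Vdr at 8 h stood at 125 ± 12 CPM in vehicle, 72.3 ± 1.9 in the libraries labelled 1,25D, 254 ± 6.9 in those labelled LPA and 223 ± 16 with both agents (mean ± SD). Groups were kept as labelled. The single treatments are therefore called the libraries labelled LPA and the libraries labelled 1,25D throughout, and every direction drawn for them carries this reservation. The comparison of both agents with vehicle and the interaction would be the same if the labels of the single treatments were exchanged.

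**Figure D1:**
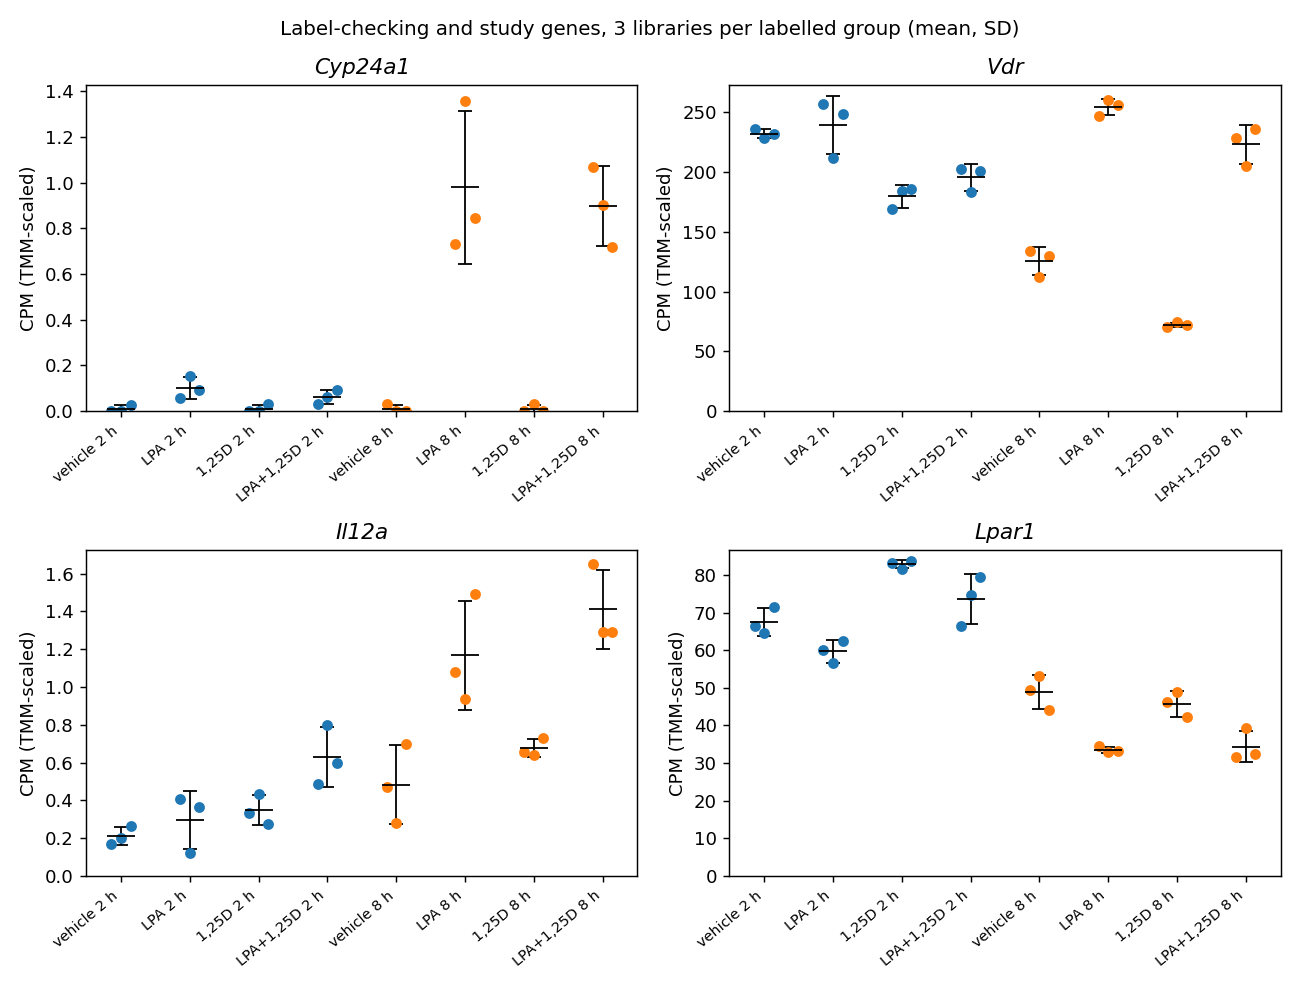
Normalised expression of Cyp24a1, Vdr, Il12a and Lpar1 (CPM) for each of the 24 libraries, by labelled group; points are libraries, dashes are means and bars are SD. At 8 h Cyp24a1 and Vdr are high in the libraries labelled LPA and in those given both agents, while Vdr is lowest in the libraries labelled 1,25D.

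Fgf23 was almost absent from these libraries. It had 0 to 5 counts per library and did not pass the filter for testing. At 8 h the summed counts were 3 for vehicle, 1 for the libraries labelled 1,25D, 4 for those labelled LPA and 6 for both agents. The ratios to vehicle were 0.337 (95% counting interval 0.00642 to 4.2), 1.31 (0.222 to 8.94) and 2.1 (0.448 to 13), so a change was not detectable at this depth. If the single effects added on the linear scale, both agents together would give 0.0188 CPM at 8 h, and the mean was 0.0609, a difference of 0.0421 ± 0.056 with 5 of the 6 counts in replicate 1. A limit of 3 counts corresponds to 0.084 to 0.097 CPM in single libraries, and such intervals and limits cover counting error only.

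Il12a, which encodes the p35 subunit of interleukin 12, rose with both agents at 2 h (log2 fold change 1.55 ± 0.41 SE, adjusted p = 0.0084) and at 8 h (1.53 ± 0.36, adjusted p = 0.0041). In the libraries labelled LPA it rose at 8 h (1.26 ± 0.36, adjusted p = 0.025), with 0.48 ± 0.43 at 2 h (adjusted p = 0.62). In the libraries labelled 1,25D the values were 0.71 ± 0.42 at 2 h (adjusted p = 0.33) and 0.47 ± 0.37 at 8 h (adjusted p = 0.43). Mean levels at 8 h were 0.484 CPM in vehicle, 0.674 labelled 1,25D, 1.17 labelled LPA and 1.41 with both agents. An additive expectation on the linear scale was 1.36 CPM at 8 h and 0.432 at 2 h, against 1.41 and 0.627 measured, differences of 0.049 ± 0.24 and 0.195 ± 0.14. The interaction on the log2 scale was 0.36 ± 0.59 at 2 h and −0.20 ± 0.50 at 8 h, neither past the threshold. Lpar1, which encodes the LPA1 receptor, fell at 8 h in the libraries labelled LPA (−0.54 ± 0.09) and with both agents (−0.50 ± 0.09), and rose by 0.30 ± 0.09 in the libraries labelled 1,25D at 2 h.

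The libraries labelled LPA differed little from vehicle at 2 h. Largest changes, here and below, are those among named genes with a mean of at least 1 CPM over the compared groups. Klhl33 rose most, by 2.39 ± 0.12 on the log2 scale (adjusted p = 7e-11; 24.1 ± 0.85 against 4.6 ± 0.22 CPM). Fst, which encodes the activin antagonist follistatin, rose by 1.27 ± 0.07, and Spp1, which encodes the bone matrix protein osteopontin, by 1.21 ± 0.10. Kcne4 (1.73), Gdpd5 (1.30), Neu3 (1.25) and Gprc5a (1.23) were also among the 8 largest rises. The falls were smaller and led by Zc3h6 (−0.66 ± 0.15), Entpd6 (−0.65), Nfkbie (−0.65), which encodes an inhibitor of NF-kB, and Egr2 (−0.64), an immediate early transcription factor gene. They were followed by Slc22a21 (−0.62), Sart3 (−0.50), Dhx35 (−0.45) and Dlc1 (−0.45). For every gene given as one of the largest changes against a single group, the replicate values of the compared groups did not overlap, a criterion that chance meets in 10% of genes with 3 libraries against 3.

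Among the gene lists fixed beforehand, vitamin D receptor targets were higher than other genes in the libraries labelled LPA at 2 h (camera adjusted p = 0.0011, and p = 0.014 with an estimated correlation), with 2 of 15 tested members higher, or 4 adjusted over the list alone. Of 22 tested genes of ERK MAPK feedback and targets, 4 rose (6 adjusted over the list alone, with 4 lower), among them the MAP kinase phosphatase genes Dusp6 (1.09 ± 0.08) and Dusp1 (0.87 ± 0.11). That list as a whole did not pass camera (adjusted p = 0.11). NF-kB targets and chemokines were lower as a group (camera adjusted p = 0.024, but p = 0.079 with an estimated correlation), with 1 of 26 members higher and 1 lower (2 and 3 adjusted over the list alone). In all, 129 of 16424 tested genes passed adjusted p 0.05 in edgeR's quasi-likelihood test, 98 higher and 31 lower, and across genes the fold changes had a rank correlation of 0.42 with the main axis of variation within groups. This count was 293 with DESeq2, 373 without a filter on low counts (185 higher and 188 lower), 739 with a covariate for variation within groups, and 69, 82 and 71 without vehicle replicate 1 and replicates 2 and 3 labelled LPA. The covariate was derived from these same genes, so larger counts with it, here and below, are not independent evidence of more changes.

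In the libraries labelled 1,25D, a broad set of immediate early and inflammatory genes was raised at 2 h. Il6, which encodes interleukin 6, rose by 4.02 ± 0.45 on the log2 scale (adjusted p = 1.4e-06; 3.81 ± 0.92 against 0.231 ± 0.06 CPM). The transcription factor genes Egr3 (3.51 ± 0.24), Npas4 (3.31 ± 0.44), Nr4a1 (3.03 ± 0.17) and Egr2 (141 ± 14 against 17.6 ± 0.87 CPM, adjusted p = 1.3e-14), the epidermal growth factor family gene Ereg (3.48 ± 0.18) and Trib1 (3.10 ± 0.16) were also among the 8 largest rises. The largest falls were smaller: Ints9 (−1.84 ± 0.47, with a wide spread of 14.5 ± 15 CPM), Epor (−1.58 ± 0.31), Bmf (−1.52 ± 0.19), B3gnt8 (−1.44), Pla2g4b (−1.37), Atoh8 (−1.37) and Rab3a (−1.35). Sprr2a2 (−1.70 ± 0.34) belongs to a family of near-identical genes, so its value is uncertain. Vdr fell by 0.37 on the log2 scale (adjusted p = 0.0018).

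Of 23 immediate early genes, 22 rose in this comparison (22 adjusted over the list alone; camera adjusted p = 5.1e-41, and p = 0.0016 with an estimated correlation), including Btg2 (2.33 ± 0.09). ERK MAPK feedback and target genes rose in 15 of 22 cases (15 adjusted over the list alone; camera adjusted p = 6.7e-21, and p = 0.00026 with an estimated correlation), with Errfi1 at 2.90 ± 0.08 and Dusp6 at 2.27 ± 0.08. NF-kB targets and chemokines rose in 22 of 26 cases (24 adjusted over the list alone; camera adjusted p = 1.3e-26, and p = 2.8e-07 with an estimated correlation), with Ptgs2, which encodes cyclooxygenase 2, at 2.80 ± 0.10 and Nfkbiz at 1.53 ± 0.08. Actin genes driven by SRF and MRTF rose in 14 of 22 cases (19 adjusted over the list alone; camera adjusted p = 1.7e-15, and p = 0.0024 with an estimated correlation), with Vcl at 0.96 ± 0.06 and Lima1 at 0.94 ± 0.08. Targets of YAP and TEAD rose in 9 of 21 cases (10 adjusted over the list alone), led by Ccn2 (1.83 ± 0.10) and F3 (1.73 ± 0.09); the camera adjusted p was 1.6e-07, but p = 0.14 with an estimated correlation. Cytokines and receptors of the IL-12 and IL-6 families rose in 9 of 20 cases and fell in 1 (9 and 1 adjusted over the list alone), with Lif at 2.56 ± 0.12 and Socs3 at 2.33 ± 0.24; the camera adjusted p was 6.4e-06, but p = 0.22 with an estimated correlation. Mitosis genes fell in 10 of 24 cases (14 adjusted over the list alone), with Plk1 at −0.66 ± 0.07 and Cdc20 at −0.47 ± 0.07; the camera adjusted p was 4.5e-07, but p = 0.33 with an estimated correlation. Vitamin D receptor targets rose in 5 of 15 cases and fell in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.027, but p = 0.1 with an estimated correlation), with the calcium pump gene Atp2b1 at 1.04 ± 0.07 and Spp1 at 0.58 ± 0.10. Osteocyte markers rose in 6 of 18 cases (6 adjusted over the list alone; camera adjusted p = 0.02, but p = 0.26 with an estimated correlation), with Cd44 at 0.94 ± 0.07 and Gja1, which encodes connexin 43, at 0.76 ± 0.09. In all, 2285 genes passed the threshold, 1160 higher (250 by at least 2-fold) and 1125 lower (69 by at least 2-fold). The count was 4180 with the covariate for variation within groups and 1487 without replicate 2 labelled 1,25D.

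With both agents at 2 h, genes differed from vehicle in both directions. Nxph3, which encodes a neurexophilin, rose by 4.62 ± 0.45 (adjusted p = 1.1e-07; 4.1 ± 0.2 against 0.164 ± 0.11 CPM). Ereg (3.67 ± 0.18), Trib1 (3.24 ± 0.16), Cebpd (3.24 ± 0.26), Npas4 (3.15 ± 0.44), Fosb (3.14 ± 0.21) and Il6 (3.05 ± 0.45) were also among the 8 largest rises, as was Vmn1r43 (3.97 ± 0.58), a member of a large receptor family whose reads could be shared between copies. The largest falls included B3gnt8 (−1.90), Ppp1r3c (−1.83), Gper1 (−1.72), the bone transcription factor gene Dlx5 (−1.63), Dmrt2 (−1.63), Efna4 (−1.49 ± 0.09) and Wnt9a (−1.49 ± 0.46). Spp1 rose by 2.16 ± 0.10, and Tnfsf11, which encodes the osteoclast-activating cytokine RANKL, rose by 1.58 ± 0.28. Vdr fell by 0.25 on the log2 scale.

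Immediate early genes rose in 22 of 23 cases (22 adjusted over the list alone; camera adjusted p = 1.9e-31, and p = 0.0044 with an estimated correlation), for example Fosl1 (2.09 ± 0.09) and Btg2 (2.54 ± 0.09). Of the ERK MAPK list, 16 of 22 genes rose and 2 fell (16 and 2 adjusted over the list alone; camera adjusted p = 1.2e-16, and p = 0.00066 with an estimated correlation), with Errfi1 at 2.92 ± 0.08 and Dusp6 at 2.83 ± 0.08. NF-kB targets rose in 18 of 26 cases (21 adjusted over the list alone; camera adjusted p = 6.5e-19, and p = 1.4e-06 with an estimated correlation), with Ptgs2 at 2.67 ± 0.10. The SRF and MRTF list rose in 17 of 22 cases (17 adjusted over the list alone; camera adjusted p = 2.2e-13, and p = 0.0044 with an estimated correlation), with Vcl at 1.18 ± 0.06 and Fhl2 at 1.10 ± 0.08. Vitamin D receptor targets rose in 6 of 15 cases and fell in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.00061, and p = 0.01 with an estimated correlation). The IL-12 and IL-6 family list rose in 10 of 20 cases (10, with 1 lower, adjusted over the list alone), with Lif at 2.54 ± 0.12 and Osmr at 0.70 ± 0.07; the camera adjusted p was 7.2e-06, but p = 0.22 with an estimated correlation. Mitosis genes fell in 8 of 24 cases (12 lower and 1 higher adjusted over the list alone), with Plk1 at −0.91 ± 0.07; the camera adjusted p was 4.2e-05, but p = 0.51 with an estimated correlation. Heat shock genes rose in 4 of 12 cases (7 adjusted over the list alone), with Hsph1 at 0.54 ± 0.09; the camera adjusted p was 0.0044, but p = 0.32 with an estimated correlation. LPA receptors and genes of LPA metabolism moved both ways, with 3 of 19 higher and 7 lower (3 and 7 adjusted over the list alone; median 0.09 but mean −0.06 and camera downward, adjusted p = 0.54), including Lpar2 at −0.95 ± 0.14. In all, 3267 genes passed the threshold, 1623 higher (355 by at least 2-fold) and 1644 lower (100 by at least 2-fold). With the covariate for variation within groups 5428 passed it.

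Adding the agent labelled LPA to the agent labelled 1,25D moved few genes at 2 h. Klhl33 rose by 3.29 ± 0.14 over the libraries labelled 1,25D (adjusted p = 1.3e-12; 21.5 ± 1.1 against 2.2 ± 0.41 CPM). Mfsd2a (1.87), Kcne4 (1.73), Nxph3 (1.65) and Mmp13 (1.62 ± 0.18), which encodes collagenase 3, also rose. Egr2 fell by 1.11 on the log2 scale, and Foxa1 (−1.10), Lbh (−0.83), Pdk4 (−0.68) and Sgk1 (−0.59) were the other large falls. Of vitamin D receptor targets, 2 of 15 rose (2 adjusted over the list alone; camera adjusted p = 0.00061, and p = 0.01 with an estimated correlation). NF-kB targets and chemokines were lower as a group (camera adjusted p = 0.01, and p = 0.042 with an estimated correlation), with 1 of 26 higher and 1 lower (1 and 4 adjusted over the list alone). Immediate early genes were lower as a group, with 2 of 23 lower (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0091, but p = 0.6 with an estimated correlation). Of 98 genes higher in the libraries labelled LPA than in vehicle, 61 were also higher in this comparison, which shares no library with it, where 0.597 would be shared by independent lists. Of 31 lower genes, 7 were shared, against 0.0491. In all, 126 genes passed the threshold, 100 higher and 26 lower. The count was 202 with DESeq2, 258 without the filter, 617 with the covariate for variation within groups, and 74 and 77 without replicate 3 labelled 1,25D and replicate 2 with both agents.

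Adding the agent labelled 1,25D to the agent labelled LPA raised immediate early, NF-kB, ERK MAPK and actin genes at 2 h. Il6 rose by 3.58 ± 0.47 over the libraries labelled LPA (adjusted p = 1.1e-05; 1.94 ± 0.21 against 0.159 ± 0.02 CPM), followed by Egr3 (3.23), Fosb (3.22), Npas4 (3.22) and Ereg (3.17). Sh2d3c (−1.57), Dnajc28 (−1.49), the iron exporter gene Slc40a1 (−1.42), Bcl7a (−1.42) and Gper1 (−1.36) fell most. NF-kB targets rose in 24 of 26 cases (25 adjusted over the list alone; camera adjusted p = 8.2e-25, and p = 2.8e-07 with an estimated correlation), including Cxcl1 at 1.90 ± 0.11. Immediate early genes rose in 22 of 23 cases (22 adjusted over the list alone; camera adjusted p = 8e-35, and p = 0.003 with an estimated correlation). ERK MAPK genes rose in 17 of 22 cases and fell in 1 (19 and 1 adjusted over the list alone; camera adjusted p = 1.3e-18, and p = 0.00042 with an estimated correlation). The SRF and MRTF list rose in 18 of 22 cases (20 adjusted over the list alone; camera adjusted p = 4.5e-16, and p = 0.0023 with an estimated correlation). Of the genes that passed in the libraries labelled 1,25D against vehicle, 938 of 1160 higher and 810 of 1125 lower genes passed the threshold in the same direction here, against 107 each for independent lists, with no library in common. In all, 3072 genes passed the threshold, 1515 higher (330 by at least 2-fold) and 1557 lower (89 by at least 2-fold). No setting or left-out library moved this count by over 1.5 times. Without the filter 1915 were higher and 1187 lower.

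The interaction at 2 h asked whether both agents together differed from the sum of the single log2 effects. It passed the threshold for 6 genes, 4 higher and 2 lower, and for 714 at an unadjusted p under 0.05. Fst (−0.62 ± 0.10, adjusted p = 0.018) and Tsc22d1 (−0.64 ± 0.11, adjusted p = 0.021) were lower than that sum. Sprr2a2 (2.94 ± 0.47) and Eif4a-ps4 (1.08 ± 0.18) were higher, but near-identical copies make both uncertain. The mitochondrially encoded genes were lower as a group (camera adjusted p = 0.0042, but p = 0.58 with an estimated correlation), with 0 of 13 members past the threshold in edgeR. Osteoblast and bone matrix genes were higher as a group (camera adjusted p = 0.024, but p = 0.22 with an estimated correlation), also with 0 of 20 past it. The number of genes was 88 without the filter, 17 with the covariate and 1 when fitted on the 4 groups alone. DESeq2 called 9. The edgeR count was 0 without vehicle replicate 1, replicate 1 labelled 1,25D, any of the 3 replicates labelled LPA, or replicate 1 or 2 with both agents, and 1 without replicate 2 or 3 labelled 1,25D.

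At 8 h the libraries labelled LPA differed from vehicle in both directions. Elfn1 rose by 6.64 ± 0.42 (adjusted p = 2.2e-10; 27.8 ± 3.3 against 0.272 ± 0.079 CPM), and Inmt, which encodes an indole methyltransferase, by 5.73 ± 0.26. Bhmt (5.90 ± 0.65) and Cbs (5.19 ± 0.18), which encode the homocysteine enzymes betaine-homocysteine methyltransferase and cystathionine beta-synthase, rose together with Krt17 (5.43 ± 0.36), Enpp3 (4.09 ± 0.12) and Klhl33 (3.89 ± 0.13). Mrgprd had 248 counts over the 3 libraries against 2 in vehicle, a ratio of 122 with a 95% counting interval from 33.4 to 1010. The falls included Lrrc17 (−1.80 ± 0.26), Ppp1r3c (−1.77), Tnfrsf11b (−1.70 ± 0.33), which encodes the RANKL decoy osteoprotegerin, Id1 (−1.59), Gpr39 (−1.55), Gper1 (−1.47) and Dlx5 (−1.45). Vdr rose by 1.02 ± 0.08 (adjusted p = 3.9e-09).

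Vitamin D receptor targets rose in 8 of 15 cases in these libraries (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.8e-07, and p = 0.00053 with an estimated correlation), including Spp1 (2.58 ± 0.10), the pyrophosphate-generating enzyme gene Enpp1 (2.79 ± 0.17) and Tnfsf11 (2.79 ± 0.30). The list of FGF23 production and phosphate handling had 3 of 14 higher (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.042, but p = 0.21 with an estimated correlation). In the ERK MAPK list, 8 of 22 rose and 3 fell (11 and 3 adjusted over the list alone), with Dusp6 at 1.55 ± 0.08, Etv5 at 1.07 ± 0.08 and Hbegf at −0.96 ± 0.13; the camera adjusted p was 0.00045, but p = 0.14 with an estimated correlation. In the Wnt signalling and bone remodelling list, 8 of 21 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.027, but p = 0.53 with an estimated correlation). Cholesterol synthesis and uptake genes fell in 10 of 22 cases and rose in 1 (14 and 1 adjusted over the list alone), with Cyp51 at −0.72 ± 0.07 and Insig1 at −0.55 ± 0.07; the camera adjusted p was 9.9e-06, but p = 0.26 with an estimated correlation. Interferon response genes fell in 7 of 22 cases (10 adjusted over the list alone), with Ifit3 at −0.83 ± 0.12 and Irf1 at −0.59 ± 0.08; the camera adjusted p was 3.8e-07, but p = 0.24 with an estimated correlation. Glycolysis and glucose uptake genes fell in 6 of 22 cases and rose in 2 (14 and 2 adjusted over the list alone; camera adjusted p = 0.0016, but p = 0.51 with an estimated correlation). LPA receptors and genes of LPA metabolism included 3 risers and 5 fallers among 19 (3 and 7 adjusted over the list alone; camera adjusted p = 0.14), with the phosphatase gene Plpp3 at 1.14 ± 0.10 and Enpp2, which encodes autotaxin, at −0.56 ± 0.09.

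In all, 1971 genes passed the threshold between the libraries labelled LPA and vehicle at 8 h, 1088 higher (365 by at least 2-fold) and 883 lower (63 by at least 2-fold). The split was 1222 and 1541 without replicate 1 labelled LPA, and 1169 and 1251 after correction for GC content and length. Of the genes passed at 2 h, 86 of 98 higher and 11 of 31 lower genes passed the same way at 8 h, against 6.49 and 1.67 for independent lists. Across genes, which are not independent replicates, the fold changes had a rank correlation of −0.50 with the main axis of variation within groups, on which vehicle replicate 2 at 8 h lay at 56.2 and replicate 2 labelled LPA at −36.1. The count was 3006 without the filter, 565 when fitted on the compared groups alone, 1067 and 3302 without vehicle replicates 2 and 3, and 1051 without replicate 2 labelled LPA.

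At 8 h the libraries labelled 1,25D had higher ERK MAPK and NF-kB genes than vehicle. The largest rises were Sema7a (2.97 ± 0.26, adjusted p = 9.8e-08; 8.75 ± 0.88 against 1.11 ± 0.48 CPM), the chromatin protein gene Hmga1 (2.68 ± 0.20), the ERK-responsive transcription factor gene Etv4 (2.38 ± 0.25), Il1rl1 (2.35 ± 0.12), which encodes the interleukin 33 receptor, and Mmp13 (2.31 ± 0.20). Krt13 (2.21), Col5a3 (2.19) and Ltbp2 (2.12) followed. The largest falls were P2rx6 (−2.89 ± 0.38), Tgm5 (−2.30 ± 0.30), Adhfe1 (−1.76), Gprc5c (−1.73), Stab2 (−1.70), Cdk15 (−1.65), S100b (−1.53) and Cideb (−1.50). Vdr fell by 0.80 on the log2 scale (adjusted p = 4.7e-07), while Spp1 rose by 1.43 ± 0.10 and the matrix Gla protein gene Mgp by 0.93 ± 0.10.

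Immediate early genes rose in 18 of 23 cases (21 adjusted over the list alone), with Nr4a3 at 2.06 ± 0.19 and Fosl1 at 1.72 ± 0.09; the camera adjusted p was 3.4e-14, but p = 0.079 with an estimated correlation. ERK MAPK feedback and target genes rose in 16 of 22 cases (17 adjusted over the list alone; camera adjusted p = 1.5e-12, and p = 0.0024 with an estimated correlation), with Errfi1 at 1.18 ± 0.08 and Etv5 at 0.83 ± 0.08. NF-kB targets and chemokines rose in 17 of 26 cases (19 adjusted over the list alone; camera adjusted p = 2.3e-13, and p = 1.3e-05 with an estimated correlation), with Traf1 at 1.88 ± 0.16 and the chemokine gene Ccl2 at 1.32 ± 0.12. Vitamin D receptor targets rose in 5 of 15 cases and fell in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0085, and p = 0.047 with an estimated correlation). The SRF and MRTF list rose in 11 of 22 cases (14 adjusted over the list alone), with Tagln at 0.99 ± 0.10; the camera adjusted p was 8.9e-05, but p = 0.15 with an estimated correlation. YAP and TEAD targets rose in 9 of 21 cases (13 adjusted over the list alone; camera adjusted p = 5.6e-06, but p = 0.22 with an estimated correlation). Mitosis genes fell in 5 of 24 cases (10 adjusted over the list alone; camera adjusted p = 1e-05, but p = 0.44 with an estimated correlation), and DNA replication and G1/S genes fell in 4 of 24 (6 adjusted over the list alone; camera adjusted p = 0.02, but p = 0.53 with an estimated correlation). Interferon response genes fell in 6 of 22 cases (8 lower and 1 higher adjusted over the list alone), with Ifit3 at −0.90 ± 0.12 and Psmb9 at −0.87 ± 0.15; the camera adjusted p was 0.0011, but p = 0.52 with an estimated correlation. Across genes, the rank correlation of these fold changes with the axis of variation within groups was −0.38. Of the genes passed at 2 h, 497 of 1160 higher and 302 of 1125 lower genes passed the same way at 8 h (91.5 and 93.6 for independent lists). The opposite direction passed for 17 and 6, with a correlation of 0.21 across all tested genes. In all, 2662 genes passed the threshold, 1296 higher (234 by at least 2-fold) and 1366 lower (91 by at least 2-fold). Without the filter 2129 were higher and 1058 lower. The count was 1287 when fitted on the compared groups alone, 1518 without vehicle replicate 2, and 1720 and 1649 without replicates 2 and 3 labelled 1,25D.

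Both agents together at 8 h changed genes in both directions against vehicle. Inmt rose by 5.99 ± 0.26 over vehicle (adjusted p = 1.9e-13; 29.6 ± 2.9 against 0.461 ± 0.12 CPM), Elfn1 by 5.83 ± 0.42, Krt17 by 5.64 ± 0.36 and Cbs by 4.29 ± 0.18. Mmp13 rose by 5.64 ± 0.21 (82.2 ± 10 against 1.65 ± 0.14 CPM) and Mmp10, which encodes stromelysin 2, by 5.60 ± 0.93. Hp (4.78 ± 0.38), which encodes haptoglobin, and Nxph3 (4.34 ± 0.47) also rose. The largest falls were Gprc5c (−2.93 ± 0.41), Tgm5 (−2.59), P2rx6 (−2.52), Lrrc17 (−2.52), Dlx5 (−2.32 ± 0.25), Colq (−2.24), S100b (−2.08) and Fgf18 (−1.85). Vdr rose by 0.83 ± 0.08 and Spp1 by 3.83 ± 0.11.

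Vitamin D receptor targets rose in 9 of 15 cases with both agents at 8 h (10 adjusted over the list alone; camera adjusted p = 5.1e-09, and p = 0.00021 with an estimated correlation), with Enpp1 at 3.54 ± 0.17 and Tnfsf11 at 2.25 ± 0.31. The list of FGF23 production and phosphate handling had 5 of 14 higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.01, but p = 0.093 with an estimated correlation). ERK MAPK genes rose in 11 of 22 cases and fell in 1 (13 and 2 adjusted over the list alone; camera adjusted p = 8.2e-08, and p = 0.015 with an estimated correlation), with Dusp6 at 2.10 ± 0.08 and Etv5 at 1.78 ± 0.08. NF-kB targets rose in 12 of 26 cases (12 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.7e-07, and p = 0.00038 with an estimated correlation), with Traf1 at 1.96 ± 0.16 and Nfkbiz at 1.17 ± 0.08. Immediate early genes rose in 12 of 23 cases and fell in 2 (12 and 2 adjusted over the list alone), with Fosl1 at 1.63 ± 0.09 and Egr2 at −0.96 ± 0.11; the camera adjusted p was 0.00054, but p = 0.52 with an estimated correlation. Glycolysis and glucose uptake genes rose in 10 of 22 cases and fell in 1 (12 and 1 adjusted over the list alone), with Eno1 at 0.55 ± 0.10 and Pfkfb3 at 0.54 ± 0.09; the camera adjusted p was 0.0069, but p = 0.53 with an estimated correlation. Interferon response genes fell in 8 of 22 cases (8 adjusted over the list alone), with Ifit3 at −0.99 ± 0.12 and Psmb9 at −0.82 ± 0.15; the camera adjusted p was 0.0018, but p = 0.53 with an estimated correlation. Osteoblast and bone matrix genes did not move as a group, with 2 of 20 higher and 5 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.53). In all, 2758 genes passed the threshold, 1567 higher (378 by at least 2-fold) and 1191 lower (154 by at least 2-fold). Across genes, the rank correlation of these fold changes with the axis of variation within groups was −0.02. Of the genes passed with both agents at 2 h, 658 of 1623 higher and 370 of 1644 lower genes passed the same way here (155 and 119 for independent lists). The count was 988 when fitted on the compared groups alone and 4946 with the covariate for variation within groups.

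**Figure D2:**
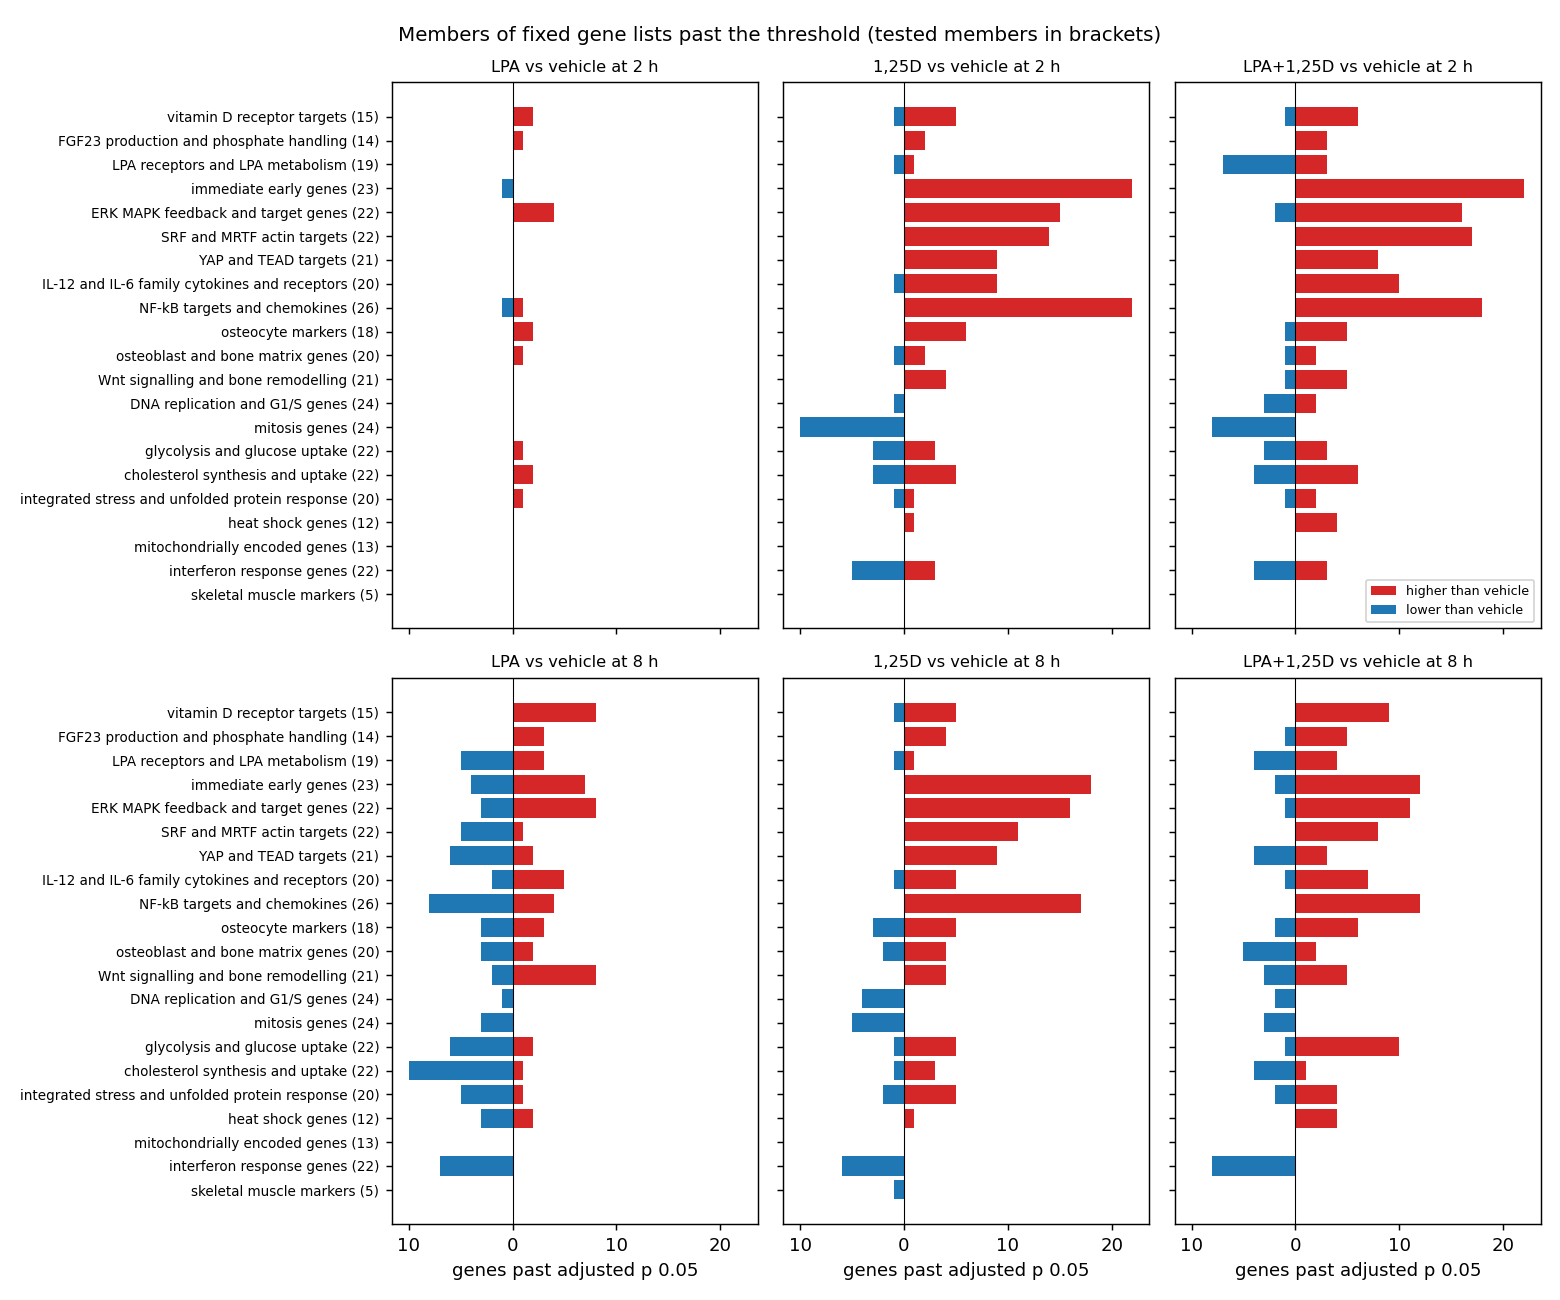
Number of tested members past adjusted p 0.05 in each of the 21 fixed gene lists with at least 5 tested members, in the 6 comparisons of a treatment with vehicle; bars to the right are members higher than vehicle and bars to the left members lower, from 3 libraries per labelled group. At 2 h immediate early genes rise in 22 of 23 cases in the libraries labelled 1,25D and in those given both agents.

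Against the libraries labelled 1,25D, those given both agents at 8 h differed in both directions. Inmt rose by 6.17 ± 0.26 (adjusted p = 1.9e-13; 29.6 ± 2.9 against 0.406 ± 0.1 CPM), Krt17 by 5.36, Cbs by 4.69, Elfn1 by 4.05 and Enpp3 by 3.86. Tnfrsf11b fell by 2.00 on the log2 scale, with Kif26b (−1.93), Dlx5 (−1.80), Trabd2b (−1.77) and the ERK antagonist gene Spry1 (−1.72). Vitamin D receptor targets rose in 7 of 15 cases (7 adjusted over the list alone; camera adjusted p = 4.1e-06, and p = 0.0013 with an estimated correlation), with Vdr at 1.63 ± 0.08 and Spp1 at 2.40 ± 0.10. Il6 had 1 count against 14, a ratio of 0.0741 with a 95% counting interval from 0.00175 to 0.487. YAP and TEAD targets fell in 10 of 21 cases and rose in 1 (11 and 1 adjusted over the list alone), with Ccn1 at −0.77 ± 0.11; the camera adjusted p was 4.2e-05, but p = 0.26 with an estimated correlation. Of the genes that passed in the libraries labelled LPA against vehicle, 427 of 1088 higher and 209 of 883 lower genes passed the same way here (62.5 and 30.3 for independent lists). In all, 1507 genes passed the threshold, 943 higher and 564 lower, and the rank correlation with the axis of variation within groups was 0.42. The count was 2386 without the filter, with 880 higher and 1506 lower. It was 807 on the compared groups alone, 2312 with the covariate, 975, 954 and 886 without replicates 1, 2 and 3 labelled 1,25D, and 897 without replicate 2 with both agents.

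Against the libraries labelled LPA, those given both agents at 8 h stood higher in NF-kB and actin genes. Mmp10 rose by 5.34 ± 0.91 (adjusted p = 0.00023; 2.1 ± 0.75 against 0.0472 ± 0.082 CPM), Il1rl1 by 2.94 ± 0.12, Steap4 by 2.65, Tspan11 by 2.59 and Ttll11 by 2.42. Flrt1 (−2.00), Clca2 (−1.96), Wscd2 (−1.95), Crocc2 (−1.86) and Sned1 (−1.62) fell most. NF-kB targets rose in 14 of 26 cases (16 adjusted over the list alone; camera adjusted p = 5.7e-09, and p = 0.00015 with an estimated correlation), with Traf1 at 2.21 ± 0.17 and Ccl2 at 1.49 ± 0.12. The SRF and MRTF list rose in 13 of 22 cases (15 adjusted over the list alone; camera adjusted p = 7e-08, and p = 0.035 with an estimated correlation), with Tagln at 1.29 ± 0.10. Glycolysis genes rose in 13 of 22 cases and fell in 2 (13 and 2 adjusted over the list alone), with Ldha at 0.98 ± 0.11; the camera adjusted p was 6.6e-06, but p = 0.26 with an estimated correlation. Genes of the integrated stress and unfolded protein response rose in 11 of 20 cases (12 adjusted over the list alone), with Psat1 at 0.71 ± 0.09; the camera adjusted p was 8.9e-05, but p = 0.26 with an estimated correlation. Cyp24a1 (−0.13 ± 0.49, adjusted p = 0.88) and Vdr (−0.19 ± 0.08, adjusted p = 0.082) did not pass. Of the genes that passed in the libraries labelled 1,25D against vehicle, 508 of 1296 higher and 450 of 1366 lower genes passed the same way (182 and 122 for independent lists). The opposite direction passed for 21 and 18, with a correlation of 0.13 across all tested genes. In all, 3765 genes passed the threshold, 2301 higher (169 by at least 2-fold) and 1464 lower (177 by at least 2-fold). The rank correlation with the axis of variation within groups was 0.47. Without the filter 1831 were higher and 2142 lower. The count was 1263 on the compared groups alone, 2445 without the 2 libraries highest on the axis of variation within groups, 1943 without replicate 2 labelled LPA, and 1972 without replicate 2 with both agents.

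The interaction at 8 h passed the threshold for 1262 genes, 667 higher and 595 lower than the sum of the single log2 effects, and for 5739 at an unadjusted p under 0.05. Of the 1262, 15 were at least 2-fold higher than the sum and 271 at least 2-fold lower. Among the largest, Krtap1-5 (1.53 ± 0.30, adjusted p = 0.018), Sgpp2 (1.38 ± 0.39), Il33 (1.28 ± 0.23) and F13a1 (1.25 ± 0.31) were higher than the sum, with the pseudogene Mageb7-ps (1.07 ± 0.24), whose reads could belong to a related copy. Elfn1 (−2.59 ± 0.58), Flrt1 (−2.28 ± 0.48), the chondrogenic transcription factor gene Sox9 (−1.92 ± 0.33), Wscd2 (−1.74 ± 0.32) and the activity-regulated gene Arc (−1.71 ± 0.24) were lower. Vdr was 0.61 ± 0.11 above the sum (adjusted p = 0.01, but 0.1 when fitted on the 4 groups alone). On the linear scale it was 223 CPM against 201 if additive, a difference of 22.2 ± 12. Interferon response genes were above it in 4 of 22 cases (8 adjusted over the list alone), with Ifit3 at 0.73 ± 0.17; the camera adjusted p was 5.7e-05, but p = 0.38 with an estimated correlation. Wnt and bone remodelling genes were below it in 6 of 21 cases (10 lower and 1 higher adjusted over the list alone), with Lef1 at −1.32 ± 0.28; the camera adjusted p was 0.00058, but p = 0.26 with an estimated correlation. Immediate early genes were below it in 5 of 23 cases and above it in 1 (13 and 3 adjusted over the list alone), with Jun at −1.36 ± 0.31; the camera adjusted p was 0.00038, but p = 0.51 with an estimated correlation. None of the genes named here for the interaction at 8 h kept the call in all 21 settings. Across genes, the interaction had a rank correlation of 0.62 with the axis of variation within groups, on which vehicle replicate 2 (56.2) and replicate 2 with both agents (45.3) lay highest. The count was 3451 with DESeq2 (1554 higher and 1897 lower), 3094 without the filter (772 and 2322), 13 on the 4 groups alone, 440 from length-scaled TPM counts, 1900 after correction for GC content and length, 487 with the axis as a covariate (94 and 393) and 25 without those 2 libraries (10 and 15). Without single libraries it was 48 and 4167 (vehicle replicates 2 and 3), 119, 78 and 44 (replicates 1, 2 and 3 labelled 1,25D), 3703, 32 and 47 (replicates 1, 2 and 3 labelled LPA), and 201, 30 and 4203 (replicates 1, 2 and 3 with both agents).

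**Figure D3:**
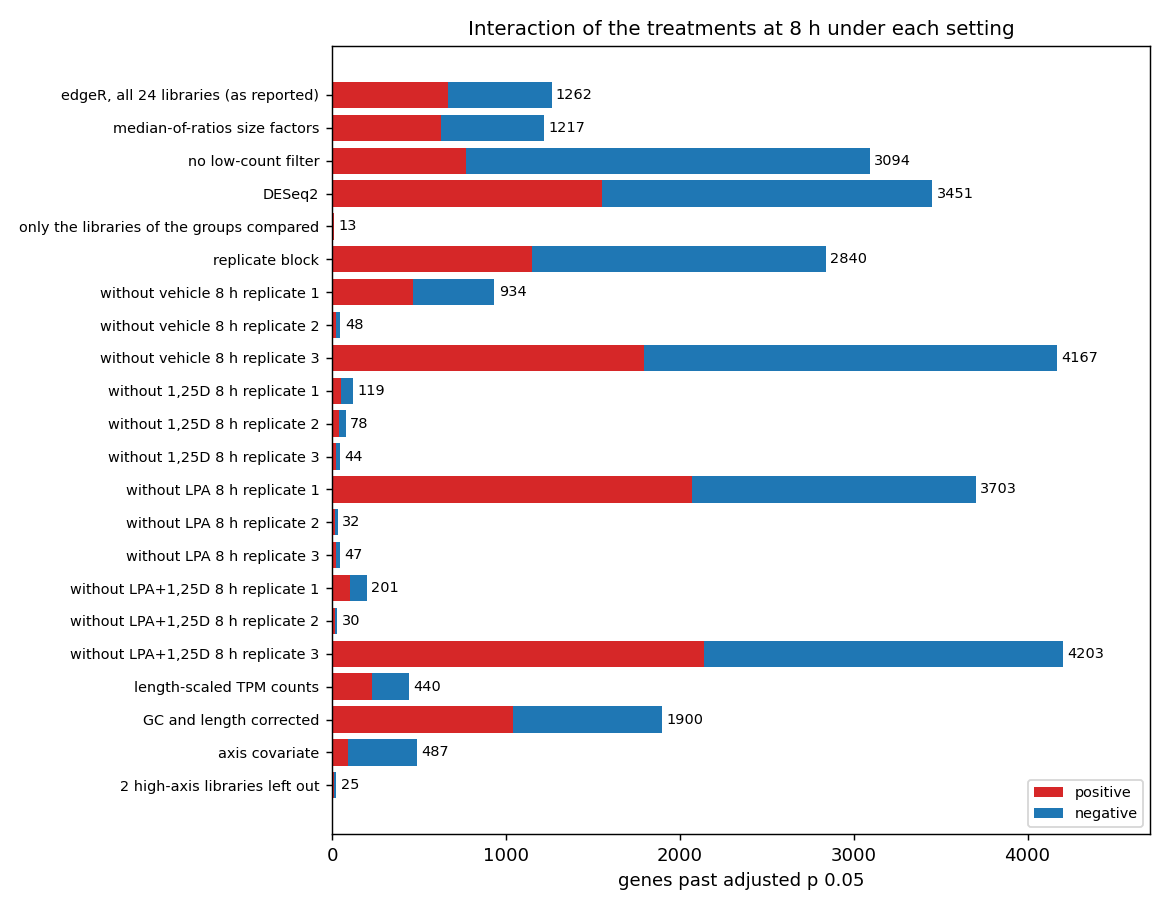
Number of genes past adjusted p 0.05 for the interaction at 8 h under each setting, positive and negative values stacked; the top bar is the count as reported, 1262, from 3 libraries per group. The count runs from 13 to 4203.

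Vehicle cultures themselves changed between 2 h and 8 h. Ankrd37 rose by 2.92 ± 0.33 (adjusted p = 2.4e-06; 2.86 ± 0.59 against 0.375 ± 0.23 CPM), with Gpr35 (2.41), the adenylate kinase gene Ak4 (2.32) and Saa3 (1.77), which encodes a serum amyloid A protein. Nr4a3 fell by 3.09 on the log2 scale, and Ccl2 (−2.11), Cxcl1 (−2.00), Ccn2 (−1.94) and Ereg (−1.81) were also lower at 8 h. Immediate early genes fell in 18 of 23 cases (19 adjusted over the list alone), NF-kB targets in 19 of 26 (22 lower and 1 higher adjusted over the list alone) and cholesterol genes in 15 of 22 (17 lower and 1 higher adjusted over the list alone), with Hsd17b7 at −0.97 ± 0.07. Mitosis genes rose in 14 of 24 cases (16 adjusted over the list alone), with Nusap1 at 0.60 ± 0.09. Mitochondrially encoded genes rose in 3 of 13 cases (5 adjusted over the list alone), and their share of counts was 13.553 ± 3.385% at 8 h against 10.597 ± 1.379% at 2 h, with 16.92% in vehicle replicate 2 at 8 h. No test of whole lists was made between times. In all, 2393 genes passed the threshold, 965 higher and 1428 lower. The count was 413 on the compared groups alone and 4158 with the covariate for variation within groups.

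The effect of each treatment was compared between 8 h and 2 h. In the libraries labelled LPA the difference passed for 1110 genes, 617 with a higher value at 8 h, led by Bhmt (5.33 ± 1.05), Elfn1 (5.08 ± 0.73), Cbs (4.05), Inmt (3.86) and Enpp3 (3.24 ± 0.16), and 493 with a lower value, led by Gpr39 (−1.56 ± 0.22), Hey2 (−1.54), Ankrd37 (−1.54), Ch25h (−1.53) and Lrrc17 (−1.51). Cholesterol genes had a lower effect at 8 h in 8 of 22 cases and a higher one in 1 (11 and 1 adjusted over the list alone). This count was 2306 with DESeq2, 3065 without the filter, 443 on the compared groups alone and 726 from length-scaled TPM counts. It was 535 without vehicle replicate 1 and 468 and 669 without replicates 2 and 3 labelled LPA at 2 h. For libraries at 8 h it was 431 and 3368 without vehicle replicates 2 and 3, and 2293, 378 and 659 without replicates 1, 2 and 3 labelled LPA, with 974 higher and 1319 lower in the fit that gave 2293. Across genes, the rank correlation of these differences with the axis of variation within groups was −0.58.

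In the libraries labelled 1,25D the difference passed for 685 genes, 219 with a higher value at 8 h, led by Tspan11 (2.47 ± 0.47), Rnf150 (2.42), Abhd15 (2.19), Etv4 (2.11) and Ppp1r3d (1.95), and 466 with a lower value, led by P2rx6 (−2.79 ± 0.50), Egr3 (−2.73), Egr2 (−2.56 ± 0.14), Reps2 (−2.38) and Fosb (−2.22). Immediate early genes had a lower effect at 8 h in 15 of 23 cases (16 adjusted over the list alone) and ERK MAPK genes in 11 of 22, with 3 higher (13 and 4 adjusted over the list alone). The count was 1046 without the filter (621 higher and 425 lower), 373 from length-scaled TPM counts, 2077 with the covariate for variation within groups (1092 and 985) and 449 without vehicle replicate 1 at 2 h. With both agents the difference passed for 1590 genes, 915 with a higher value at 8 h, led by Inmt (4.16 ± 0.45), Elfn1 (3.73), Cbs (3.56), Enpp3 (2.97) and Galnt15 (2.92), and 675 with a lower value, led by Egr3 (−3.46 ± 0.34), Egr2 (−2.84 ± 0.15), Inhba (−2.77), Fosb (−2.73) and Tgm5 (−2.40). Immediate early genes had a lower effect at 8 h in 17 of 23 cases (19 adjusted over the list alone). That count was 743 on the compared groups alone, 980 from length-scaled TPM counts and 3510 with the covariate.

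Part of the markers of other cell types passed the filter for testing. Over all genes 16424 of 49172 did, so the shares below do not show that such markers were scarce. Adipocyte markers had 3 of 9 genes tested, chondrocyte markers 4 of 10, macrophage and blood cell markers 4 of 11, endothelial markers 4 of 8 and skeletal muscle markers 5 of 9. With both agents against vehicle at 8 h, the numbers past the threshold in edgeR were 0 for adipocyte, chondrocyte, endothelial and skeletal muscle markers, and 1 higher for macrophage and blood cell markers (2 higher and 1 lower adjusted over the list alone, and 1 lower for skeletal muscle). In the other comparisons at most 1 member of such a list passed in either direction (at most 3 adjusted over the list alone). Against vehicle, 1 chondrocyte marker was higher in the libraries labelled 1,25D at both times, with both agents at 2 h and in the libraries labelled LPA at 8 h (1 each adjusted over the list alone). At 8 h 1 macrophage and blood cell marker was higher in the libraries labelled LPA (1 higher and 1 lower adjusted over the list alone). In those labelled 1,25D, 1 such marker and 1 skeletal muscle marker were lower (1 each adjusted over the list alone). With both agents against the libraries labelled LPA, 1 chondrocyte and 1 skeletal muscle marker were higher at 2 h (1 each adjusted over the list alone). The same comparison at 8 h had 1 macrophage and 1 endothelial marker higher and 1 chondrocyte marker lower (1, 1 and 2 adjusted over the list alone). Against those labelled 1,25D at 8 h, 1 macrophage marker was higher and 1 chondrocyte marker lower (3 and 1 adjusted over the list alone). Only the skeletal muscle list had enough tested members for camera (adjusted p = 0.33). Over all lists, 85 of 252 pairs of list and comparison passed camera with the preset correlation, and 26 of them passed with an estimated correlation.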

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

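The time differences below come from a planned test, while the tests of the treatment labels and the alternatives used for the interaction (the axis covariate, the correction for GC content and length, and leaving out 2 libraries) were chosen after seeing the data.

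A difference between times drew attention in each treatment, tested as the log2 effect against vehicle at 8 h minus that at 2 h (edgeR, adjusted p under 0.05). The difference passed for 1110 of 16424 tested genes in the libraries labelled LPA, and 8 of 100 assignments of the libraries had as many, counting the real one beside 99 random ones that mix treatments and times. The genes below were named in part for this difference, so their number says nothing of how common it is. Some of the higher values below were falls at 2 h that did not pass at 8 h. They were Entpd6 (−0.65 at 2 h, 0.19 at 8 h), Zc3h6 (−0.66, 0.15), Sart3 (−0.50, 0.14), Slc22a21 (−0.62, 0.02) and Dhx35 (−0.45, 0.14). These genes were named among the largest falls at 2 h, and the effect of that choice was not tested. The effect was higher at 8 h for Bhmt (5.33), Elfn1 (5.08), Cbs (4.05), Inmt (3.86), Enpp3 (3.24), Gdpd5 (1.99), Enpp1 (1.86), Tnfsf11 (1.79), Fst (1.65), Klhl33 (1.5), Spp1 (1.38), Plpp3 (1.09), Vdr (0.98), Entpd6 (0.84), Zc3h6 (0.81), Sart3 (0.64), Slc22a21 (0.63), Gprc5a (0.62), Dhx35 (0.60), Etv5 (0.55) and Dusp6 (0.46). It was lower at 8 h for Irf1 (−0.44), Insig1 (−0.47), Cyp51 (−0.70), Enpp2 (−0.72), Hbegf (−0.75), Ifit3 (−0.92), Gper1 (−1.11), Id1 (−1.19), Lrrc17 (−1.51), Ch25h (−1.53), Ankrd37 (−1.54), Hey2 (−1.54) and Gpr39 (−1.56).

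The difference passed for 685 of 16424 tested genes in the libraries labelled 1,25D, and 6 of 100 assignments of the libraries had as many, counting the real one beside 99 random ones that mix treatments and times. The effect was higher at 8 h for Tspan11 (2.47), Rnf150 (2.42), Abhd15 (2.19), Etv4 (2.11), Ppp1r3d (1.95), Col5a3 (1.73), Pla2g4b (1.59), Ltbp2 (1.52), Hmga1 (1.49), Bmf (1.41), Mmp13 (1.01), Il1rl1 (0.93), Spp1 (0.85), Etv5 (0.73), Rab3a (0.73), Mgp (0.59) and Plk1 (0.37). It was lower at 8 h for Vdr (−0.42), Fosl1 (−0.53), Cd44 (−0.54), Atp2b1 (−0.59), Vcl (−0.68), Ccl2 (−0.84), Lima1 (−0.89), Gja1 (−0.91), Psmb9 (−0.98), Nfkbiz (−1.04), Ccn2 (−1.18), Trib1 (−1.32), Adhfe1 (−1.49), Dusp6 (−1.60), F3 (−1.68), Lif (−1.69), Nr4a1 (−1.70), Errfi1 (−1.72), Ereg (−1.81), Btg2 (−1.88), Ptgs2 (−2.11), Tgm5 (−2.21), Fosb (−2.22), Reps2 (−2.38), Egr2 (−2.56), Egr3 (−2.73) and P2rx6 (−2.79). Some of the higher values were falls at 2 h that did not pass at 8 h. They were Abhd15 (−1.70 at 2 h, 0.49 at 8 h), Pla2g4b (−1.37, 0.22) and Bmf (−1.52, −0.12). Rab3a (−1.35, −0.62) and Plk1 (−0.66, −0.29) fell less at 8 h. Lower values include rises at 2 h that were smaller at 8 h, such as Dusp6 (2.27, 0.67). Pla2g4b and Bmf were named among the largest falls at 2 h, and the effect of that choice was not tested.

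The difference passed for 1590 of 16424 tested genes in the libraries given both agents, and 7 of 100 assignments of the libraries had as many, counting the real one beside 99 random ones that mix treatments and times. The effect was higher at 8 h for Inmt (4.16), Elfn1 (3.73), Cbs (3.56), Enpp3 (2.97), Galnt15 (2.92), Mmp13 (2.72), Enpp1 (2.37), Spp1 (1.67), Dmrt2 (1.61), Efna4 (1.37), Vdr (1.08), Etv5 (0.92), Traf1 (0.76), Plk1 (0.60) and Eno1 (0.59). It was lower at 8 h for Fosl1 (−0.46), Pfkfb3 (−0.46), Fhl2 (−0.52), Lpar1 (−0.63), Dusp6 (−0.73), Trib1 (−0.90), Psmb9 (−0.99), Vcl (−1.05), Colq (−1.05), Ereg (−1.11), Errfi1 (−1.31), S100b (−1.54), Btg2 (−1.55), Ptgs2 (−1.60), Lif (−1.73), Lrrc17 (−1.85), P2rx6 (−1.91), Tgm5 (−2.40), Fosb (−2.73), Inhba (−2.77), Egr2 (−2.84), Egr3 (−3.46) and Il6 (−5.43). The value for Il6 rests on 1 count at 8 h. Among the higher values, Dmrt2 (−1.63 at 2 h, −0.02 at 8 h) and Efna4 (−1.49, −0.12) fell past the threshold at 2 h alone. These genes were named among the largest falls at 2 h, and the effect of that choice was not tested. Plk1 (−0.91, −0.31) fell less at 8 h. Lower values include rises past the threshold at 2 h alone, such as Vcl (1.18, 0.13).

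Cyp24a1 and Vdr went against the labels of the single treatments. If 1 library were mislabelled, its Cyp24a1 count would stand apart from its group, and 0 of the 6 libraries labelled LPA or 1,25D at 8 h did so by more than 5 times. If the agents acted as labelled, vitamin D receptor targets would be higher in the libraries labelled 1,25D, and 5 of 15 were at 8 h (Spp1, Atp2b1, Enpp1, Mgp and Cd14). The prediction asked for 1 or more, and 16.2% of all tested genes passed in that comparison, so it could hardly fail. In those labelled LPA 8 of 15 were higher. Of the 5, Spp1, Enpp1 and Mgp had higher means labelled LPA than labelled 1,25D, while Atp2b1 and Cd14 had lower ones. The counts therefore do not favour the labels as given, and the question stays open. The list holds Vdr itself, which had raised the question, so these counts are in part not independent of it. An exchange of the labels LPA and 1,25D between the single treatments may account for the pattern: Cyp24a1 with both agents was −0.13 ± 0.49 against the libraries labelled LPA, while against those labelled 1,25D it had 87 counts to 1. The treatment letters in the names of the deposited tables also carry that exchange, and the sources used here do not decide it.

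The interaction at 8 h called 1262 genes, with 1 of 100 assignments of the 12 libraries to the 4 groups reaching as many (the real one) and 1253 as the highest other, but the 99 random assignments mix treatment groups and do not show what no change would give, so they cannot exclude chance. A trend on GC content and transcript length is argued against as the whole source, since 997 of the genes stayed called after correction and the median absolute log2 value went from 0.58 to 0.56. With the axis of variation within groups as covariate 409 genes stayed called, with a median of 0.36, but this cannot decide whether the axis is the source. Mean scores on it at 8 h were 14.9 for vehicle, 10.2 for both agents, −10.5 labelled 1,25D and −14.0 labelled LPA. These lie along the contrast itself, so the covariate takes calls away whether or not the axis is the cause. Without the 2 libraries highest on that axis all 1262 genes kept their direction, with a median of 0.42, but 25 genes were called with 2 fewer libraries, which leaves open what those libraries contribute. A joint action of the treatments on a core of genes also stays open, as 8 genes were called in all 21 settings, among them Net1 (0.81 ± 0.10), Rgl1 (0.62), Mical2 (−0.80), Tgfb3 (0.69), F3 (0.86), Ptgfr (1.02) and Mindy1 (0.56).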

How the results depend on the processing

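The counts from length-scaled TPM, the correction for GC content and length, the axis covariate and leaving out 2 high-axis libraries were chosen after seeing the data, and the other alternatives were planned. The axis came from the genes tested, so larger counts with that covariate are not independent evidence of more changes. Of 765 named values past the threshold, 524 stayed past it in every alternative and 241 lost the call in at least 1. Over 13063 alternative values, 1 reversed the sign of a value past the threshold. Hsd17b7, for the effect labelled LPA at 8 h against 2 h, went from 0.34 to −0.13 with length-scaled TPM counts. Sign changes of named values not past the threshold were not counted. Lost calls, counted per value and fit, were 771 over the left-out libraries, 164 with the compared groups alone, 89 with length-scaled TPM, 71 without 2 libraries, 57 without the filter, 37 after GC and length correction, 28 with the axis covariate, 5 with DESeq2 and 1 with median-of-ratios scaling. Fits on fewer libraries have fewer degrees of freedom. On the compared groups alone, counts of 1 group against another stayed within 1.5 times at 2 h. At 8 h all of them fell by more, so this loss alone does not account for the fall. Replicates at 8 h differed unequally, with chi-square per degree of freedom of 27.9 to 134 in vehicle and 7.09 to 8.83 labelled 1,25D. The shared estimate of the spread can thus overstate calls for groups of wide spread. Otherwise the cause was not tested. Depth limited Fgf23 and Cyp24a1 in vehicle, where 3 counts are 0.084 to 0.097 CPM, and in simulated data 38.8% of 1.5-fold changes were recovered.

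Below, counts stand against the reported ones, with the share of higher genes in both where it moved by over 10 points. Without the low-count filter they were 373 against 129 (labelled LPA at 2 h, share 49.6 against 76%), 258 against 126 (both against labelled 1,25D at 2 h), 88 against 6 (interaction at 2 h), 3006 against 1971 (labelled LPA at 8 h, 74.9 against 55.2%), 2386 against 1507 (both against labelled 1,25D at 8 h, 36.9 against 62.6%), 3094 against 1262 (interaction at 8 h, 25 against 52.9%), 3065 against 1110 (time difference labelled LPA, 75.9 against 55.6%) and 1046 against 685 (time difference labelled 1,25D, 59.4 against 32%). The share also moved without the filter for both against labelled LPA at 2 h (61.7 against 49.3%) and 8 h (46.1 against 61.1%) and for labelled 1,25D at 8 h (66.8 against 48.7%). DESeq2 called 293 (labelled LPA at 2 h, 57.7%), 202 (both against labelled 1,25D at 2 h, 68.3 against 79.4%), 3451 (interaction at 8 h) and 2306 (time difference labelled LPA). On simulated data 20.2% of its calls were false for labelled LPA at 8 h and 15.9% for the interaction at 8 h, against 4.8 and 5.66% in edgeR. The simulation held no variation shared by genes, so these rates need not hold for the real libraries.

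Fitted on the compared groups alone, the counts were 1 (interaction at 2 h, share 100 against 66.7%), 565 (labelled LPA at 8 h, 71.9%), 1287 (labelled 1,25D at 8 h), 988 (both at 8 h), 807 and 1263 (both against labelled 1,25D and labelled LPA at 8 h), 13 (interaction at 8 h, 69.2%), 413 (vehicle between times, 29.8 against 40.3%), 443 and 743 (time differences labelled LPA and with both). For labelled 1,25D at 2 h the share was 62.7 against 50.8%. With the axis covariate they were 739 (labelled LPA at 2 h, 56.4%), 4180 (labelled 1,25D at 2 h), 5428 (both at 2 h), 617 (both against labelled 1,25D at 2 h, 59.6%), 17 (interaction at 2 h), 4946 (both at 8 h), 2312 (both against labelled 1,25D at 8 h), 487 (interaction at 8 h, 19.3%), 4158 (vehicle), 2077 (time difference labelled 1,25D, 52.6%) and 3510 (with both), and the share was 66.6% for the time difference labelled LPA. Length-scaled TPM gave 440 (interaction at 8 h), 726, 373 and 980 (time differences labelled LPA, labelled 1,25D and with both) and a share of 85.7% for the interaction at 2 h. GC and length correction gave 1900 (interaction at 8 h). Without 2 high-axis libraries there were 2445 (both against labelled LPA at 8 h) and 25 (interaction at 8 h, 40%), and a share of 66.9% for the time difference labelled LPA. The list tests fell from 85 to 26 with an estimated correlation.

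Left-out libraries moved the share to 87, 86.6 and 88.7% for labelled LPA at 2 h (vehicle replicate 1, replicates 2 and 3 labelled LPA), 89.6% for both against labelled 1,25D at 2 h (replicate 2 with both), 44.2% for labelled LPA at 8 h (replicate 1 labelled LPA), and 42.5 and 66.1% for the time difference labelled LPA (replicate 1 labelled LPA and vehicle replicate 2, both at 8 h). For the interaction at 2 h these fits had at most 7 genes and a share from 0 to 100%. Leaving out each library gave 69 to 96 genes for labelled LPA at 2 h, 1487 to 2084 for labelled 1,25D, 2414 to 2814 for both, 74 to 107 and 2168 to 2886 for both against labelled 1,25D and LPA, and 0 to 7 for the interaction (edgeR, where the full set had 714 at unadjusted p under 0.05 and DESeq2 called 9). At 8 h the ranges in that order were 1051 to 3302, 1518 to 3408, 2043 to 2748, 886 to 1936, 1943 to 4263 and 30 to 4203. They were 1606 to 2642 for vehicle between times, 378 to 3368, 449 to 797 and 1145 to 1628 for the time differences labelled LPA, labelled 1,25D and with both, and 81 to 92 for the list tests.

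Whether the replicate numbers pair the samples was not settled. Libraries of the same number and time correlated from −0.25 to 0.36 after removal of group means, and libraries of unlike number were not compared. On the axis of variation within groups, replicate 2 at 8 h deviated from its group mean by 41.3 in vehicle and 35.1 with both agents. The deviation was 0.4 labelled 1,25D and −22.1 labelled LPA. With the number as a block the interaction at 8 h had 2840 genes (share 40.4%) and the interaction at 2 h a share of 50%, and no other count moved by over 1.5 times. The block lost 15 calls.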

Other observations

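The hypoxia list was chosen after the vehicle time comparison was seen, and the split counts were planned.

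Bone cell genes moved both ways when both agents were set against the libraries labelled 1,25D at 8 h. Dmp1, which encodes the osteocyte matrix protein DMP1, rose by 1.03 ± 0.17 and Fbln7 by 0.77 ± 0.07, while Runx2, the osteoblast transcription factor gene, fell (−0.68 ± 0.18). Sfrp4, which encodes a Wnt antagonist, rose by 1.81 ± 0.44 and Lef1, a Wnt effector gene, fell (−1.53 ± 0.21). Osteocyte markers had 4 of 18 higher and 5 lower (5 and 6 adjusted over the list alone), with a camera adjusted p of 0.96, and the Wnt and bone remodelling list 4 of 21 higher and 5 lower (5 and 7 adjusted over the list alone), with 0.078.

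Vehicle cultures at 8 h had higher Ankrd37 and Ak4 than at 2 h, both known as hypoxia-inducible. As a hypothesis, oxygen in the cultures may have been lower at 8 h. A list of 18 other hypoxia-inducible genes had a median log2 change of 0.34, above 100% of 10000 random lists matched on expression, whose central 95% ran from −0.19 to 0.10. Such random lists make no allowance for correlation between genes. Of these genes 10 were higher and 1 lower, with Egln3 at 1.27 ± 0.24, Bnip3 at 1.16 ± 0.15, Slc2a1 at 1.05 ± 0.11, Kdm3a at 0.52 ± 0.09 and Pfkfb4 at −0.36 ± 0.10, while 7 did not pass, among them Vegfa (−0.16, adjusted p = 0.61) and Car9 (−0.28, adjusted p = 0.21). The list was not tested without vehicle replicate 2 at 8 h, which stood apart at 56.2 on the axis of variation within groups. Handling or medium effects between the harvests were not tested.

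Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. In each, 1 split, the real one, had as many genes. The highest other split had 1 gene against 129 for labelled LPA at 2 h and 1252 against 2758 for both agents against vehicle at 8 h, where vehicle replicates 1 and 2 stood with replicate 2 of both agents. It had 0 in edgeR against 2285 (labelled 1,25D at 2 h), 3267 (both at 2 h), 126 and 3072 (both against labelled 1,25D and LPA at 2 h), 1971 and 2662 (labelled LPA and 1,25D at 8 h), 1507 and 3765 (both against labelled 1,25D and LPA at 8 h) and 2393 (vehicle between times). For the interaction and time differences 100 assignments were used, the real one and 99 random ones. Counting the real one, as many genes came in 8 of 100 for the interaction at 2 h (highest other 1961 against 6), 1 of 100, the real one, at 8 h (1253 against 1262), 8 of 100 for the time difference labelled LPA (2471 against 1110), 6 of 100 labelled 1,25D (4066 against 685) and 7 of 100 with both agents (3294 against 1590). The split with 4066 follows a known structure of the samples, as it set all 6 libraries at 2 h against all 6 at 8 h. These assignments mix treatments or times, so they do not show what no change would give and cannot exclude chance or favour it. In all 21 settings 258, 247 and 531 genes kept the call for the time differences labelled LPA, labelled 1,25D and with both agents, and 8 for the interaction at 8 h, while the interaction at 2 h kept 0 in 20.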
